A study of Mus musculus with 12 samples.

How the data were processed

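The samples were thioglycollate-elicited peritoneal macrophages of C57BL/6 mice fed chow or a high-fat diet for 12 weeks from 6 weeks of age, cultured without red blood cells (RBC) or with RBC of chow-fed or high-fat-fed mice. Per the labels' protocols, RNA was isolated with RNeasy columns, amplified with the WTA-Ovation FFPE V2 kit and labelled with the Encore biotin module, and each sample went on an Affymetrix Mouse Gene ST array. The 12 arrays form 6 groups of 2. The values deposited by the authors are log2 signals per probe set and array that lie close to a common distribution on all arrays; the authors' method of summarization and normalization is not given in the sources used here. That the scale is log2 was read from the range of the values. No raw intensities or detection calls were analysed here, so signal over background is unknown, and the number of arrays limits the precision.

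Of 35557 probe sets in the deposited table, 35556 had values. The probe table lists 23410 of these and leaves 12146 unlisted. The 21789 probe sets with a single gene symbol were kept, and the 1621 with several symbols (globins among them) were tested apart. For the 999 genes with several probe sets the one with the highest mean over all arrays was used, which left 19938 genes. No filter on low values was applied. Gene positions were not used, and chromosome names come from the reference annotation.

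A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; residual df 6, prior df 7.69), and 14 contrasts were tested. These were RBC against none (averaged over both macrophage diets and for each of 4 exposed groups), high-fat against chow RBC (averaged and within each macrophage diet), high-fat against chow macrophages (averaged and within each RBC condition), and the interactions of RBC exposure and of RBC diet with macrophage diet. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes of a contrast. Errors are standard errors of the limma estimates. The 30 gene lists, with 576 of 627 members measured, were fixed beforehand from general knowledge: 20 of functions and 10 of other cell types (erythroid, neutrophil, eosinophil, B cell, T and NK cell, mast cell and basophil, platelet, dendritic cell, mesothelial and fibroblast, and adipocyte). Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry. For each list the members were also adjusted over the list alone.

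Genes are named by a rule fixed beforehand. It takes up to 12 genes up and 12 down with the largest changes in each of the 3 averaged comparisons, among those called and of the same sign in every stratum, and up to 5 and 5 in the others. It adds the 5 genes of smallest p where fewer pass, up to 4 members of a list by p, and a fixed set (Hmox1, Slc40a1, Ccl2, Tnf, Il1b, Il6, Nos2, Arg1, Abca1, Cd36 and Hba-a1, the last of which has only shared globin probe sets). The genes and lists that the text names were picked from those the rule allows after their results were seen, for biological interest (Il1b and Abca1 are also given in comparisons for which it does not name them), and the closing section gives the effect of leaving arrays out for all genes the rule allows as well. The procedure was tested on simulated data with the gene means and residual spread of these arrays and 200 changed genes, of which 100 changed by log2 0.5 and 100 by 1. At 1 it recovered 99% for RBC exposure, 99% for RBC diet, 100% for macrophage diet, 93% for RBC diet within chow macrophages and 75% for the interaction with exposure; at 0.5 it recovered 88%, 79%, 88%, 34% and 17%. Simulated errors were independent between genes, with the same spread in all groups. Correlated genes and groups of unequal spread were not simulated, nor were fewer than 200 changed genes, for which the recovered share can be lower.

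Alternatives chosen before the data were examined were an adjusted p below 0.10, a 1.5-fold minimum, quantile normalization over the tested genes, removal of the lowest 33.3% of genes by mean, an intensity trend with robust eBayes, array weights, the animal number as a block over all groups or within each macrophage diet, the mean of a gene's probe sets, a fit to the compared arrays only, and omission of each array in turn. Added after seeing the data were removal of X and Y genes, the block within diet for the gene lists, and an explicit fit without 1 array that stood apart.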

Results

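Transcripts were measured on 12 mouse arrays in thioglycollate-elicited peritoneal macrophages cultured with or without red blood cells (RBC), which macrophages engulf (erythrophagocytosis). Macrophage donors were C57BL/6 mice kept on chow or on a high-fat diet for 12 weeks from 6 weeks of age, and the RBC came from mice on either diet. Each of the 6 combinations of macrophage diet (chow or high-fat) and RBC given (none, chow or high-fat) had 2 arrays, numbered as separate animals. The small number of arrays limits the precision. Values are log2 differences ± SE from a limma fit to 19938 genes on all 12 arrays, and adjusted p values are Benjamini-Hochberg values from limma.

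What changed in macrophages given RBC of either kind was asked by comparing the 8 exposed with the 4 unexposed arrays, averaged over both macrophage diets. The exposed cultures held far more transcripts typical of blood cells. S100a9, a calcium-binding protein of neutrophils, was higher by 5.76 ± 0.09 (adjusted p = 2.4e-14), and Ppbp, a platelet chemokine, by 4.44 ± 0.18 (adjusted p = 7.9e-09). S100a9 was higher on 8 of 8 exposed arrays than on any unexposed array of the same macrophage diet. The globin probe sets, each listed for several adult globin genes and so left out of the gene test, were higher by 6.10 ± 0.15 and 6.15 ± 0.13 for alpha globin and by 7.41 ± 0.12 and 7.50 ± 0.13 for beta globin. Alas2, the first enzyme of heme synthesis in erythroid cells, rose by 1.09 ± 0.15, and Bpgm, which makes the red cell metabolite that lowers oxygen affinity, by 0.67 ± 0.08. The list of erythroid transcripts as a whole was not called: 2 of 18 rose, 0 fell and 16 did not pass (2 and 0 adjusted over the list alone), with camera adjusted p = 0.42, a median below 0 and a mean above it. Of the neutrophil markers, 7 of 15 rose, 0 fell and 8 did not pass (8 and 0 adjusted over the list alone), among them Retnlg (1.93 ± 0.09), the chemokine receptor Cxcr2 (0.96 ± 0.08) and the collagenase Mmp8 (0.91 ± 0.09). Camera adjusted p was 5.9e-08, and 0.016 with an estimated correlation. Of the platelet markers, 6 of 10 rose, 0 fell and 4 did not pass (7 and 0 adjusted over the list alone), among them the receptor Clec1b (1.00 ± 0.08), the lipoxygenase Alox12 (1.01 ± 0.11) and the adhesion receptor subunit Gp9 (0.93 ± 0.11). Camera gave adjusted p = 8.8e-07 for the platelet list, and adjusted p = 0.11 with an estimated correlation. B cell markers went the other way, since 0 of 14 rose, 5 fell and 9 did not pass (0 and 6 adjusted over the list alone). Ms4a1 was at -0.46 ± 0.09 and Cd79b at -0.37 ± 0.08 (camera adjusted p = 5.7e-04, and 0.24 with an estimated correlation). For both genes this averages over responses that differed, more positive in high-fat than in chow macrophages by 0.90 for Ms4a1 and 0.61 for Cd79b. Without replicate 2 of the unexposed chow macrophages Cd79b no longer passed (adjusted p = 0.069).

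**Figure D1:**
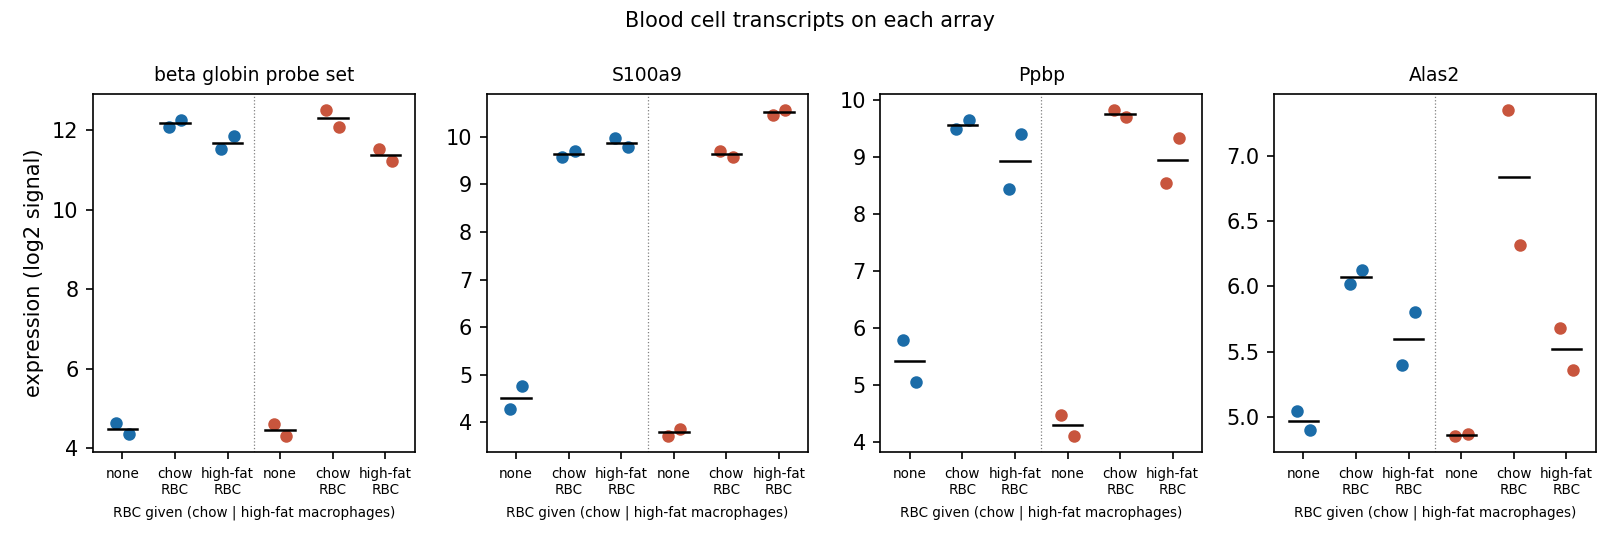
Log2 signal (vertical axis) of a beta globin probe set, S100a9, Ppbp and Alas2 on each of the 12 arrays by RBC given (horizontal axis). Points are arrays, bars are means of 2 arrays, blue marks chow and red high-fat macrophages. The beta globin means lie between 4.46 and 4.49 without RBC and between 11.38 and 12.29 with RBC.

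Apart from the genes named above, the largest rises with RBC included several genes of contractile and matricellular proteins, a group for which no list had been fixed. Whether these transcripts came from the macrophages or with the RBC was not tested. Myl9, a myosin light chain, rose by 1.78 ± 0.08, smooth muscle actin Acta2 by 1.36 ± 0.08, and the secreted matrix-associated proteins Ccn2, Thbs1 and Ccn1 by 1.68 ± 0.10, 1.55 ± 0.06 and 1.45 ± 0.08. Ctla2a (2.64 ± 0.14), Cytip (1.56 ± 0.10), Ankrd1 (1.41 ± 0.09) and Timp3, an inhibitor of metalloproteinases (1.29 ± 0.12), were among the other large rises. Most of these rises were larger in chow macrophages, with a difference (high-fat minus chow response) of -2.02 for Myl9, -1.79 for Acta2 and -1.40 for Ccn2. The difference was -1.52 for Ankrd1, -1.08 for Ccn1 and -1.07 for Cytip, and was not called for Thbs1, Ctla2a and Timp3. Of the genes of the cell cycle, 17 of 29 rose, 0 fell and 12 did not pass (20 and 0 adjusted over the list alone), with Top2a, Bub1 and Ube2c at 0.76, 0.70 and 0.60 (camera adjusted p = 1.3e-15, and 0.016 with an estimated correlation). This is an average over responses that differed between the macrophage diets (interaction adjusted p = 0.012 with an estimated correlation): in high-fat macrophages 0 of 29 passed with either RBC (camera adjusted p = 0.027 and 0.12, and 0.29 and 0.56 with an estimated correlation). The first camera call was lost without replicate 1 with chow RBC or replicate 1 or 2 of the unexposed high-fat macrophages (0.16, 0.069 and 0.11). Matrix and protease genes had 7 of 17 members higher and 1 lower (9 and 4 adjusted over the list alone; camera adjusted p = 6.9e-05, and 0.25 with an estimated correlation). Among genes lower with either RBC in both macrophage diets, the largest falls were those of Flrt3 (-1.08 ± 0.08), the metallothionein Mt2 (-0.89 ± 0.08), the stress-induced regulator Nupr1 (-0.85 ± 0.06), Radx (-0.84 ± 0.12) and the adhesion molecule Vcam1 (-0.83 ± 0.07). Asns and Mthfd2, enzymes of asparagine synthesis and of the mitochondrial folate cycle, fell by 0.79 ± 0.06 and 0.75 ± 0.07, and Sprr1a, Osbpl3, Ly6i, Slc13a3 and Tmem178 by 0.74, 0.70, 0.69, 0.68 and 0.68. Several of these falls average over responses that differed between the macrophage diets. The response in high-fat macrophages was more positive by 1.80 for Flrt3, 1.18 for Slc13a3, 1.15 for Osbpl3 and 1.00 for Ly6i. It was also more positive for Asns, Nupr1, Radx, Tmem178, Vcam1 and Mthfd2, and more negative for Mt2 (-0.60). Ly6i lay below every unexposed array of its diet on 5 of 8 exposed arrays, and Slc13a3 on 6 of 8. The unfolded protein and integrated stress response list split, with 6 of 24 members higher and 6 lower (12 and 7 adjusted over the list alone; camera adjusted p = 0.4). The protein disulfide isomerase Pdia4 rose by 0.50 ± 0.07, while Trib3 and Sesn2, like Asns targets of the transcription factor ATF4, fell by 0.56 ± 0.06 and 0.48 ± 0.07.

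Of the inflammatory cytokines and NF-kB targets, 4 of 25 rose, 10 fell and 11 did not pass (4 and 15 adjusted over the list alone). The adhesion molecule Icam1 was at -0.81 ± 0.06, the signalling adaptor Traf1 at -0.79 ± 0.07, Sod2 at -0.67 ± 0.06 and Tnf at -0.71 ± 0.07 (camera adjusted p = 4.3e-05, and 0.025 with an estimated correlation). These 4 genes lay below every unexposed array of the same diet on 4 of 8 exposed arrays each, and like the NF-kB list they average over responses that differed between the macrophage diets. Other cytokine genes rose, namely Il1b by 1.09 ± 0.09 (beyond every unexposed array of its diet on 7 of 8 arrays) and Il6 by 0.69 ± 0.10. Arg1, an arginine-degrading enzyme of alternatively activated macrophages, rose by 0.86 ± 0.09, the iron exporter gene Slc40a1 by 0.47 ± 0.09 and the cholesterol exporter gene Abca1 by 0.43 ± 0.07. For Il1b and Abca1 these are averages over responses that differed, by 1.64 and 0.77 more in high-fat than in chow macrophages, values looked up after the averages were seen. With chow and high-fat RBC, Abca1 rose by 0.83 and 0.81 in high-fat macrophages and was at 0.00 and 0.08, not called, in chow macrophages. The heme-degrading enzyme gene Hmox1 was at 0.12 ± 0.07, the scavenger receptor gene Cd36 at 0.10 ± 0.05, Ccl2 at 0.02 ± 0.11 and Nos2 at -0.08 ± 0.10, none of which passed. Ccl2 changed sign after quantile normalization (-0.02). Among antigen presentation genes, 0 of 13 rose, 4 fell and 9 did not pass (0 and 6 adjusted over the list alone), with Cd40 at -0.68 ± 0.07 and H2-Eb1 at -0.47 ± 0.10 (camera adjusted p = 1.8e-04, and 0.05 with an estimated correlation). This too averages over responses that differed (interaction adjusted p = 0.012 with an estimated correlation), since with either RBC 7 fell and 0 rose in chow macrophages, while 0 fell and 1 rose in high-fat macrophages (4 and 3 higher adjusted over the list alone; camera adjusted p = 0.061 and 0.04, and 0.22 and 0.16 with an estimated correlation). In high-fat macrophages with chow RBC that list passed without replicate 2 with chow RBC (0.019), and with high-fat RBC it did not pass without replicate 1 or 2 with high-fat RBC or replicate 2 of the unexposed (0.071, 0.088 and 0.19). H2-Eb1 no longer passed without replicate 2 of the unexposed chow or replicate 1 of the unexposed high-fat macrophages (adjusted p = 0.061 and 0.073). The iron handling list (2 of 22 higher, 2 lower; 3 and 3 adjusted over the list alone) and the NRF2 and heme response list (0 of 23 higher, 1 lower, Abcc1 at -0.35 ± 0.06; 0 and 1 adjusted over the list alone) had camera adjusted p values of 0.28 and 0.81. Interferon-stimulated genes had 2 of 28 members higher and 3 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.15), an average over responses that differed between the macrophage diets. They passed as a list without replicate 2 of the unexposed chow macrophages, of the chow macrophages with high-fat RBC or of the high-fat macrophages with high-fat RBC (adjusted p = 0.014, 0.026 and 0.044).

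In all, limma called 1480 of 19938 genes, 1042 higher and 438 lower, and 4797 had an unadjusted p under 0.05 (996.9 expected by chance). After quantile normalization 1489 were called, 57.5% of them higher in place of 70.4%. Without replicate 2 of the unexposed chow macrophages the count was 681. Without replicate 1 or 2 of the unexposed high-fat macrophages it was 899 or 2812.

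In chow macrophages alone, exposure to RBC went with lower expression of inflammatory and interferon genes. With chow RBC, the prostaglandin E synthase gene Ptges was at -3.50 ± 0.14, the chemokine genes Cxcl3 and Cxcl2 at -3.00 ± 0.22 and -2.50 ± 0.15, the itaconate-producing enzyme gene Acod1 at -2.81 ± 0.18 and the interferon-induced Ifi205 at -2.66 ± 0.12, each against 2 unexposed arrays. With high-fat RBC, Cxcl3 was at -3.73 ± 0.22, Ptges at -3.71 ± 0.14, the fatty acid receptor gene Gpr84 at -3.26 ± 0.11, Ifi205 at -3.07 ± 0.12 and Cxcl2 at -2.91 ± 0.15. Tnf, Icam1 and Traf1 fell by 1.68, 1.83 and 1.90 with chow RBC. Of the 25 NF-kB targets and cytokines, 16 fell and 1 rose with chow RBC, and 17 fell and 1 rose with high-fat RBC (17 and 21 lower adjusted over the list alone; adjusted p = 0.0029 and 0.0025 with an estimated correlation). Of the 28 interferon-stimulated genes, 20 fell with chow RBC, Oas2 by 0.88 ± 0.10, and 23 with high-fat RBC, while 0 rose (26 and 25 lower adjusted over the list alone; adjusted p = 0.049 and 0.047 with an estimated correlation). B cell markers fell along with these genes, 4 and 6 of 14, while 0 rose (adjusted over the list alone, 6 and 7 were lower and 0 and 1 higher; camera adjusted p = 0.0011 and 2.4e-05, and 0.21 and 0.1 with an estimated correlation). Cell cycle genes rose, 17 of 29 with either RBC (21 and 23 adjusted over the list alone; adjusted p = 0.011 and 0.012 with an estimated correlation). S100a9 rose by 5.12 and 5.36 with chow and high-fat RBC, Ppbp by 4.14 and 3.50, Ctla2a by 2.96 and 2.68, Myl9 by 2.77 and 2.80, and Ccn2 by 2.37 and 2.39. With chow RBC, Arg1 rose by 1.36 ± 0.15, and 6 of 23 glycolysis and hypoxia genes rose and 1 fell (6 and 1 adjusted over the list alone), among them the HIF targets Egln3 (1.32 ± 0.20), Ankrd37 (1.32 ± 0.19) and Vegfa (1.03 ± 0.15). Camera called that list (adjusted p = 0.0022), with adjusted p = 0.48 with an estimated correlation and 0.13 without replicate 1 of the chow macrophages with chow RBC.

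Limma called 1830 genes with chow RBC (1243 higher, 587 lower) and 1663 with high-fat RBC (1079 higher, 584 lower). Both comparisons share the 2 unexposed arrays and are not independent. Without replicate 1 or 2 of the chow macrophages with chow RBC the first count was 946 or 1119, and without replicate 2 of the unexposed it was 726. The second was 762 or 710 without replicate 1 or 2 of the chow macrophages with high-fat RBC, and 1108 or 720 without replicate 1 or 2 of the unexposed.

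High-fat macrophages answered with higher expression of interferon genes. With chow RBC, Rtp4, Ifit3 and Ifit1, all induced by interferon, rose by 2.65 ± 0.19, 2.42 ± 0.22 and 2.08 ± 0.20, and the prostaglandin synthase gene Ptgs2, Il1b and Bcl3 by 1.64 ± 0.12, 1.38 ± 0.15 and 1.22 ± 0.15. With high-fat RBC, the neutrophil-attracting chemokine gene Cxcl2 rose by 2.77 ± 0.15, Rtp4 by 2.66 ± 0.19 and Il1b by 2.44 ± 0.15. Of 28 interferon-stimulated genes, 12 rose with chow RBC and 7 with high-fat RBC, and 0 fell (25 and 21 higher adjusted over the list alone; adjusted p = 0.016 and 0.026 with an estimated correlation). Of 25 NF-kB targets and cytokines, 3 and 4 rose and 0 fell (12 and 9 higher adjusted over the list alone; adjusted p = 0.0072 and 0.0048 with an estimated correlation). Markers of other blood cells moved with these genes. S100a9 rose by 5.84 and 6.72, Ppbp by 5.47 and 4.65, Alox12 by 1.72 with chow RBC, and Retnlg and Cxcr2 by 2.63 and 1.13 with high-fat RBC. Apart from these markers, Ctla2a rose by 2.57 with chow RBC. Of the 10 platelet markers 5 and 3 rose with chow and high-fat RBC (6 and 6 adjusted over the list alone; adjusted p = 0.016 and 0.042 with an estimated correlation), and of the 15 neutrophil markers 4 and 6 (6 and 8 adjusted over the list alone; adjusted p = 0.0098 and 0.0035).

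The largest falls in high-fat macrophages with chow RBC were those of Mt2 (-1.52), Rasgrp3 (-0.95), Efr3b (-0.89), Etv5 (-0.92) and Tmem273 (-0.71), and with high-fat RBC those of Efr3b (-0.97), Rasgrp3 (-0.88), Mt2 (-0.85), Nav2 (-0.72) and Bcl2 (-0.67). Etv5 lost its call without replicate 2 with chow RBC (adjusted p = 0.055), and Tmem273 without replicate 1 or 2 with chow RBC or replicate 1 of the unexposed (0.16, 0.064 and 0.1). Mt2 lost it without replicate 2 with high-fat RBC (0.074), Nav2 without either array with high-fat RBC or replicate 2 of the unexposed (0.11, 0.11 and 0.06), and Bcl2 without replicate 1 with high-fat RBC or replicate 2 of the unexposed (0.16 and 0.07). Limma called 129 genes with chow RBC (111 higher, 18 lower) and 150 with high-fat RBC (129 higher, 21 lower). The first count was 54 or 65 without replicate 1 or 2 of the high-fat macrophages with chow RBC, and 80 or 458 without replicate 1 or 2 of the unexposed. The second was 80 or 66 without replicate 1 or 2 with high-fat RBC, and 93 or 290 without replicate 1 or 2 of the unexposed. Fitted to the 4 arrays of each comparison alone, the counts were 44 and 38.

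Whether the response to RBC differed with the macrophage diet was tested as an interaction (the response in high-fat minus that in chow macrophages). The same contrast is the gap between the macrophage diets with RBC minus that without, so it is not independent of the macrophage diet comparisons given below. The difference was 5.07 ± 0.18 for Cxcl2, 5.02 ± 0.22 for Acod1, 3.64 ± 0.27 for Ifit3, 3.58 ± 0.17 for Ptges and 3.55 ± 0.24 for Ifit1. It was -2.02 ± 0.16 for Myl9, -1.79 ± 0.15 for Acta2, -1.67 ± 0.16 for Cmbl, -1.52 ± 0.18 for Ankrd1 and -1.49 ± 0.16 for Bub1, with adjusted p at most 1.4e-04 among these 10 genes. Of 28 interferon-stimulated genes 26 had a more positive response in high-fat macrophages and 0 a more negative one (28 and 0 adjusted over the list alone), among them Rtp4 (3.48 ± 0.23) and Ifi205 (3.33 ± 0.14). The same held for 17 of 25 NF-kB targets and cytokines (19 and 0 adjusted over the list alone), with Traf1 at 2.40, Tnf at 2.00 and Icam1 at 2.00. It also held for 10 of 23 chemokines (2 were more negative; 14 and 2 adjusted over the list alone), such as Ccl3 (1.60), and for 7 of 13 antigen presentation genes (7 and 0 adjusted over the list alone), such as H2-Aa (1.24) and Cd86 (1.14). Of 25 immediate early genes 8 were more positive (10 and 0 adjusted over the list alone), such as Gadd45b (1.61) and Egr1 (0.73). Of 29 cell cycle genes 11 were more negative (0 and 19 adjusted over the list alone), such as Top2a (-0.99) and Cdk1 (-0.83). With an estimated correlation the adjusted p was 5.2e-04 for the NF-kB list and 0.012 for the interferon list, and all 6 lists stayed called. Limma called 1131 genes (513 more positive, 618 more negative), and 558 without replicate 2 of the unexposed chow macrophages. Across genes, which are not independent replicates, the responses in the separate arrays of the 2 macrophage diets had a Pearson r of 0.117 for chow RBC and 0.159 for high-fat RBC. Of 72 genes called in both macrophage diets with chow RBC 38 had the same sign, and of 83 called with high-fat RBC 44 did. Among those of the same sign, 36 and 42 were higher in both diets. Were the calls of the 2 diets independent, 6.92 and 6.98 would be expected.

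**Figure D2:**
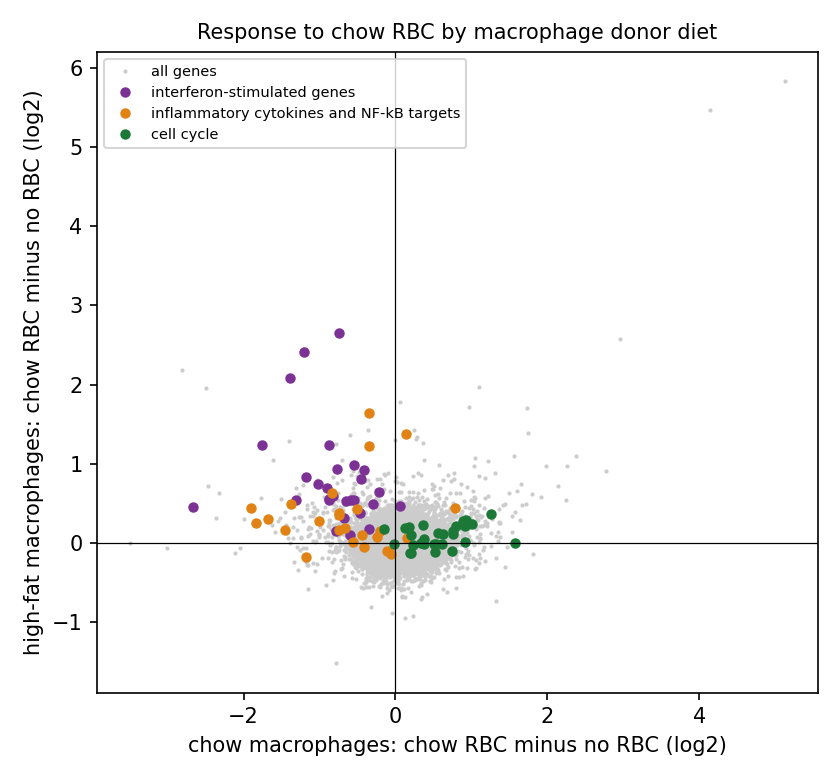
Log2 response to chow RBC of each gene in chow macrophages (horizontal axis) and in high-fat macrophages (vertical axis), 2 arrays per group. Points are genes, with interferon-stimulated, NF-kB and cell cycle list members coloured. 20 of 28 interferon-stimulated genes fell in chow and 12 rose in high-fat macrophages.

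Whether RBC from high-fat mice act differently from chow RBC was asked on the 8 exposed arrays, 4 against 4. Il1f9, which encodes the cytokine interleukin-36 gamma, was higher with high-fat RBC by 0.92 ± 0.09 (adjusted p = 8.4e-04), with 4 of 4 high-fat RBC arrays above every chow RBC array of the same macrophage diet. Its mean log2 level was 5.84 without RBC, 6.20 with chow RBC and 6.91 with high-fat RBC in chow macrophages, and 5.51, 6.78 and 7.91 in high-fat macrophages. Ifitm1, an interferon-induced membrane protein gene, was higher by 0.70 ± 0.09 (adjusted p = 0.03, 4 of 4 arrays), and its other probe set by 0.68. These were the 2 genes that passed. 629 had an unadjusted p under 0.05 (996.9 expected by chance). The next genes by p, which did not pass, were Gpr84 (-0.54 ± 0.08, adjusted p = 0.069), the hydroxybutyrate receptor gene Hcar2 (0.72 ± 0.11, adjusted p = 0.072) and Il1b (0.65 ± 0.10, adjusted p = 0.096). Of the genes fixed in advance, Slc40a1 was at 0.56 ± 0.11 (adjusted p = 0.22), while Tnf, Il6, Arg1, Abca1, Hmox1, Ccl2, Nos2 and Cd36 were at -0.06, 0.16, -0.07, 0.03, -0.03, 0.11, 0.06 and 0.11, and none passed. Il1f9 passed in every leave-one-out fit of the averaged comparison. Ifitm1 did not pass without any of the 4 arrays of exposed chow macrophages, replicate 2 of the high-fat macrophages with chow RBC or either of those with high-fat RBC (adjusted p from 0.066 to 0.24). The count was 1 without replicate 1 or 2 of the chow macrophages with chow RBC, replicate 1 of those with high-fat RBC or replicate 2 of the high-fat macrophages with high-fat RBC, and 4 (1 higher, 3 lower) without replicate 2 of the high-fat macrophages with chow RBC. The last of these fits also called Gpr84 (0.033). Hcar2 passed without replicate 1 of the same group (0.038) and Il1b without replicate 2 of the chow macrophages with high-fat RBC (0.022).

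Among the blood cell lists, those of neutrophils and platelets were called between the RBC diets, and only the former stayed called with an estimated correlation. The neutrophil list was called higher with high-fat RBC (camera adjusted p = 1.2e-06, and 0.036 with an estimated correlation), with S100a9, Lcn2, Cxcr2 and S100a8 at 0.56, 0.55, 0.45 and 0.37. 0 members passed over all genes, while adjusted over the list alone 7 of 15 were higher and 1 lower. The platelet list was called lower (camera adjusted p = 1.1e-08, and adjusted p = 0.13 with an estimated correlation; Ppbp at -0.73 and Alox12 at -0.66, 4 of 10 lower adjusted over the list alone). Alas2 was at -0.89 ± 0.17 (adjusted p = 0.22; it passed without replicate 2 of the high-fat macrophages with chow RBC, adjusted p = 0.0028), Bpgm at -0.24 and the 4 globin probe sets between -0.70 and -0.60 (adjusted p = 0.9999 for each). The interferon-stimulated and glycolysis lists were called lower (adjusted p = 5.7e-06 and 8.4e-05) and the lysosome list higher (0.019). With an estimated correlation these adjusted p values were 0.63, 0.68 and 0.98. Adjusted over the list alone, 1 interferon-stimulated, 2 glycolysis and 0 lysosome members passed. Left out in turn, replicate 1 of the chow macrophages with chow RBC took the glycolysis list to 0.29, and replicate 1 with high-fat RBC took the interferon list to 0.062 and the lysosome list to 0.15. The lysosome list was at 0.31 without replicate 2 of the chow macrophages with chow RBC, and in high-fat macrophages at 0.062 without replicate 1 with chow RBC and 0.53 without replicate 2 with high-fat RBC.

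In high-fat macrophages, 5 genes were higher with high-fat than with chow RBC: Il1f9 (1.14 ± 0.12), Ifitm1 (1.07 ± 0.13), Il1b (1.05 ± 0.15), the long noncoding RNA Mirt2 (1.00 ± 0.14) and the iron-binding protein gene Lcn2 (0.96 ± 0.13), with adjusted p between 0.0046 and 0.026. The neutrophil list was higher in the same comparison (adjusted p = 0.029 with an estimated correlation, with 6 and 0 of 15 higher and lower adjusted over the list alone), and Lcn2 is a member of it. Whether the genes called between the RBC diets, here or on average, came from macrophages or from neutrophils carried in with the RBC was not tested. The count was 2, both among the 5 genes, without either array of the chow macrophages with chow RBC, replicate 1 of the high-fat macrophages with chow RBC or replicate 1 of those with high-fat RBC. Without replicate 2 of the high-fat macrophages with chow RBC it was 2 other genes, both lower, and without replicate 2 of those with high-fat RBC it was 0. Il1f9 failed without replicate 2 with chow RBC or replicate 2 with high-fat RBC (adjusted p = 0.058 and 0.055). Ifitm1 failed without replicate 2 with chow RBC or either array with high-fat RBC (up to 0.18). Il1b and Lcn2 failed without either array of any exposed group but the chow macrophages with high-fat RBC (up to 0.36 and 0.33), and Mirt2 without 9 of the 12 arrays in turn (up to 0.31). Fitted to the arrays of this comparison alone, 0 genes passed.

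In chow macrophages limma called 0 genes between the RBC diets, and 555 had an unadjusted p under 0.05. There the HIF targets Egln3 and Ankrd37 were at -1.34 ± 0.20 and -1.13 ± 0.19 (adjusted p = 0.12 and 0.22), Gpr84 at -0.79 ± 0.11, Il1f9 at 0.71 ± 0.12 and Tnfsf9 at -0.55 ± 0.11. The glycolysis and hypoxia list was called lower (adjusted p = 4.7e-08, and adjusted p = 0.58 with an estimated correlation; 0 and 5 of 23 higher and lower adjusted over the list alone), but not without replicate 1 with chow RBC (0.16). Egln3 passed without replicate 2 of the chow macrophages with chow RBC (adjusted p = 0.0084), the 1 gene called in that fit, and 2 genes were called without replicate 1 of those with high-fat RBC. The difference between the macrophage diets in the effect of RBC diet was called by limma for 0 genes, and 718 had an unadjusted p under 0.05. Those with the smallest p were Cxcl2 (1.23 ± 0.21), Egln3 (1.59 ± 0.28), Cd226 (-0.99 ± 0.21), Greb1l (0.78 ± 0.15) and Zfp458 (0.77 ± 0.16), with adjusted p of 0.67 or more. Cxcl2 passed without either array of the unexposed high-fat macrophages (adjusted p = 0.0096 in both fits) and Egln3 without replicate 2 of the chow macrophages with chow RBC (0.029), each the 1 gene called in its fit. The 5 genes called in high-fat macrophages are thus not shown to differ from chow macrophages. By list, the glycolysis and neutrophil lists were called more positive in high-fat macrophages (adjusted p = 6.5e-04 and 0.0026; 3 of 23 and 4 of 15 members adjusted over the list alone). With an estimated correlation adjusted p was 0.93 and 0.21, and the calls were lost without replicate 1 of the chow macrophages with chow RBC (glycolysis, 0.26) or replicate 2 (neutrophil, 0.053).

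**Figure D3:**
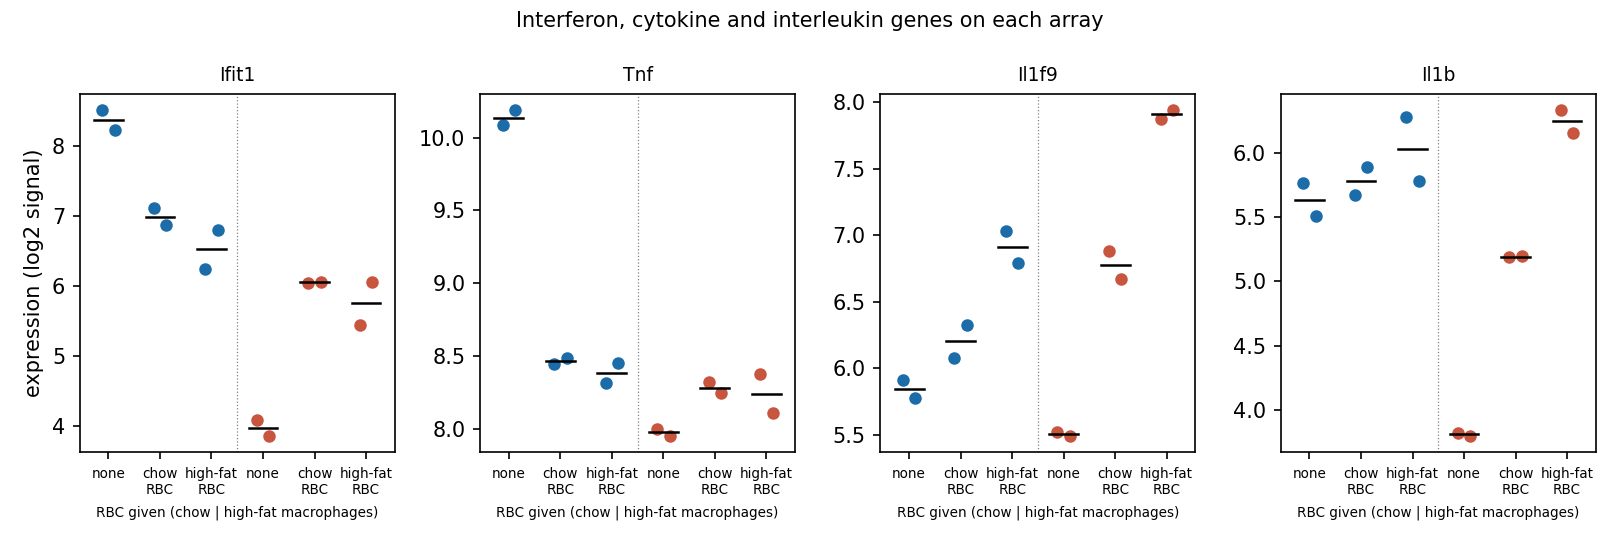
Log2 signal (vertical axis) of Ifit1, Tnf, Il1f9 and Il1b on each of the 12 arrays by RBC given (horizontal axis). Points are arrays, bars are means of 2 arrays, blue marks chow and red high-fat macrophages. Il1f9 means rise from 5.84 to 6.91 in chow and from 5.51 to 7.91 in high-fat macrophages.

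How macrophages of high-fat mice differ from those of chow mice was asked on 6 arrays each, averaged over the RBC conditions. Interferon, chemokine and antigen presentation genes were lower in high-fat macrophages. The chemokine genes Ccl5, Ccl22 and Cxcl3 were at -3.38 ± 0.08, -2.75 ± 0.13 and -2.49 ± 0.12, complement factor B (Cfb) at -3.02 ± 0.06, and the interferon-linked Ifi27l2a, Irf7 and Ifit3 at -2.95 ± 0.10, -2.68 ± 0.12 and -2.55 ± 0.13, each lower on 6 of 6 arrays. Clec4a1, Ms4a6b, Ms4a4a and Aif1 were at -2.75, -2.63, -2.50 and -2.47. Of 28 interferon-stimulated genes 27 were lower and 0 higher (0 and 27 higher and lower adjusted over the list alone), among them Oas3 (-1.42 ± 0.07). Of 13 antigen presentation genes 9 were lower (10 adjusted over the list alone), such as H2-Aa (-1.59 ± 0.06) and Cd74 (-1.76 ± 0.07). Of 23 chemokines 16 were lower and 3 higher, and of 25 NF-kB targets and cytokines 18 were lower, such as Traf1 (-1.09) and Nlrp3 (-0.86). Adjusted over the list alone, 16 and 19 were lower. Alternative activation genes went the same way (11 of 22 lower, 1 higher; 1 and 11 higher and lower adjusted over the list alone), with Arg1 at -2.36 ± 0.09 and Retnla at -2.32 ± 0.12. So did macrophage identity genes (9 of 17 lower, 1 higher; 3 and 10 adjusted over the list alone; Cd14 at -1.04, the Fc receptor gene Fcgr1 at -1.43) and immediate early genes (11 of 25 lower; 13 adjusted over the list alone; Dusp1 at -0.88, Fos at -0.49). With an estimated correlation adjusted p was between 0.0021 and 0.011 for these 7 lists.

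Sterol synthesis genes were higher in high-fat macrophages: 16 of 20 rose and 0 fell (17 and 0 adjusted over the list alone), such as Dhcr7 (0.99 ± 0.07), Idi1 (0.93 ± 0.06) and Hmgcs1 (0.64 ± 0.06), with adjusted p = 0.016 with an estimated correlation. Lipid uptake and oxidation genes had 9 of 24 higher and 1 lower, such as Hadhb (0.52) and Cpt1a (0.36), and lysosome genes 6 of 30 higher, such as Glb1 (0.33) and Gaa (0.33). The NRF2 and heme response list had 9 of 23 lower and 2 higher, such as Slc7a11 (-0.87) and Abcc1 (-0.79). Camera called these 3 lists (adjusted p = 3.1e-04, 3.7e-04 and 0.0017), with adjusted p = 0.14, 0.58 and 0.54 with an estimated correlation. Adjusted over the list alone, 12, 6 and 2 of their members were higher and 3, 0 and 10 lower. Other large rises were those of Lrmda (2.25 ± 0.10), Cacna1a (1.97 ± 0.07), Mamdc2 (1.37 ± 0.06), Scgb1a1 (1.31 ± 0.08), mitochondrial ND3 (1.21 ± 0.06), Ankrd1 (1.11), the lipoprotein-sorting receptor gene Sort1 (1.11), Hpse (1.07) and Lrrc27 (1.02). The other probe set of ND3 was higher by 0.58. Tnf, Il1b, Abca1 and Hmox1 were lower, at -0.83, -0.73, -0.45 and -0.29, and Slc40a1 was higher at 0.52. Cd36 was at 0.17 ± 0.05 (adjusted p = 0.047), a call that was lost without any 1 of the 12 arrays (adjusted p up to 0.13). Ccl2, Il6 and Nos2 were at 0.28, 0.07 and 0.02 and did not pass. Ccl2 passed without replicate 1 of the unexposed high-fat macrophages (adjusted p = 0.0044).

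Markers of sex and of B cells differed along with these genes. Xist, the RNA of the inactive X chromosome, was at -5.65 ± 0.11, between 9.07 and 9.44 on the 6 chow macrophage arrays and between 3.22 and 4.14 on the 6 high-fat arrays. The Y-linked Eif2s3y, Uty and Kdm5d were at 4.37 ± 0.07, 2.44 ± 0.11 and 2.06 ± 0.10, so that all 12 arrays split by diet as they would by sex. Of the genes called in the diet comparison, 46 of 739 X-linked genes were higher and 33 lower in high-fat macrophages, against 1328 and 1236 of 19190 autosomal genes. Of 14 B cell markers 10 were lower and 1 higher (1 and 11 higher and lower adjusted over the list alone; adjusted p = 0.028 with an estimated correlation), such as Cd79a (-1.51 ± 0.10), Cd79b (-1.19 ± 0.07) and Cd22 (0.42 ± 0.06).

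**Figure D4:**
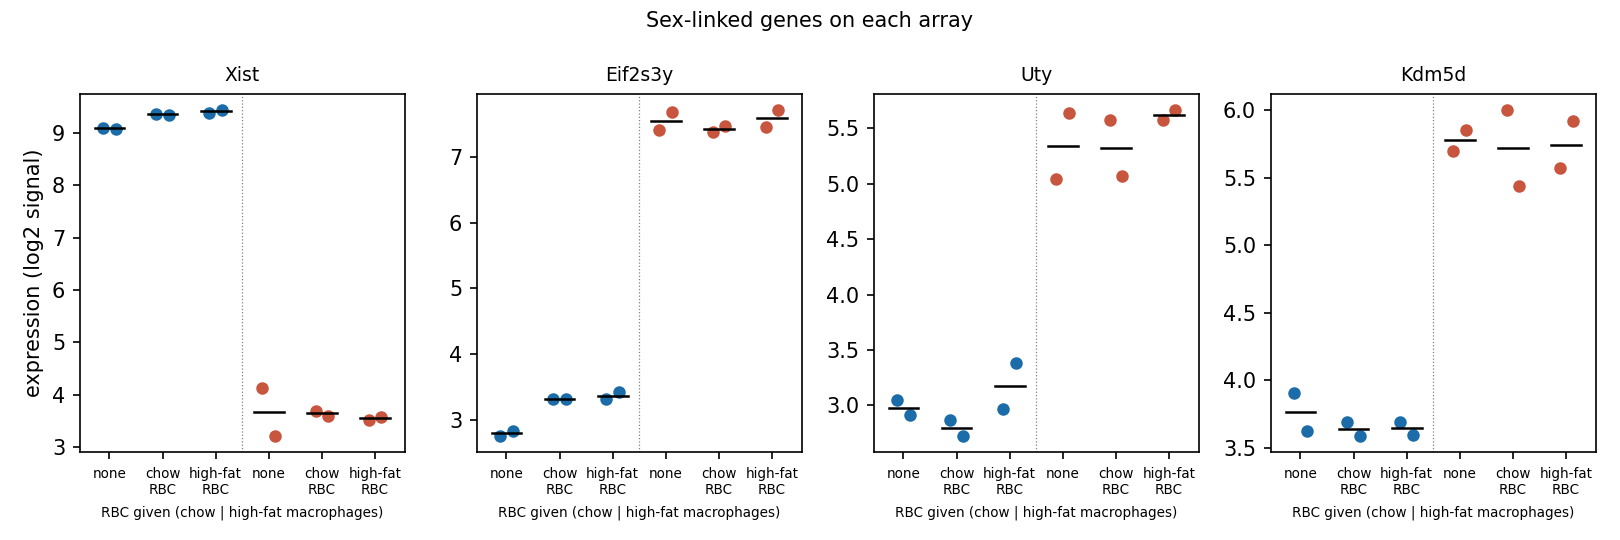
Log2 signal (vertical axis) of Xist, Eif2s3y, Uty and Kdm5d on each of the 12 arrays by RBC given (horizontal axis). Points are arrays, bars are means of 2 arrays, blue marks chow and red high-fat macrophages. The 6 chow arrays are high in Xist and low in the Y-linked genes, and the 6 high-fat arrays the reverse.

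Limma called 2648 genes between the macrophage diets averaged over the RBC conditions, 1379 higher and 1269 lower in high-fat macrophages. Without RBC it called 2780 (1619 higher, 1161 lower), with Acod1 (-5.05 ± 0.18), Cxcl2 (-5.19 ± 0.15) and Ifit3 (-4.98 ± 0.22) on the lower side, with Myl9 at 2.22 ± 0.13 on the higher. There 27 of 28 interferon-stimulated genes were lower (28 adjusted over the list alone; adjusted p = 0.0072 with an estimated correlation) and 16 of 29 cell cycle genes higher (19 adjusted over the list alone; adjusted p = 0.015 with an estimated correlation), such as Bub1 (1.34) and Cdk1 (0.87). With chow RBC it called 492 (181 higher, 311 lower), with Ccl5 at -2.92 ± 0.14 and Arg1 at -2.86 ± 0.15. With high-fat RBC it called 272 (92 higher, 180 lower), with Ccl22 at -3.03 ± 0.22 and Cfb at -2.60 ± 0.11. Interferon-stimulated genes were lower in 13 and 11 of 28 (15 and 17 adjusted over the list alone; adjusted p = 0.057 and 0.036 with an estimated correlation), and sterol synthesis genes higher in 10 and 9 of 20 (16 and 15 adjusted over the list alone; adjusted p = 0.02 and 0.017). After quantile normalization the chow RBC comparison had 596 genes, 48.2% of them higher in place of 36.8%. The count without RBC was 1600 without replicate 2 of the unexposed chow macrophages. That with chow RBC was 188 or 233 without replicate 1 or 2 of the chow macrophages and 204 or 181 without replicate 1 or 2 of the high-fat macrophages. That with high-fat RBC was 127 or 121 without replicate 1 or 2 of the chow and 139 or 161 without replicate 1 or 2 of the high-fat macrophages.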

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

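Tests of a shift by the globin signal, of donor sex and of X and Y genes were chosen after the result was seen, as was the array tested as standing apart, although leaving out each array was planned; the other tests were chosen before.

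Transcripts of blood cells rose with RBC exposure, with S100a9 going from mean log2 levels of 4.52 and 3.79 without RBC to between 9.63 and 10.51 with RBC, and Ppbp from 5.42 and 4.28 to between 8.92 and 9.76. Of 100 splits of the arrays into 8 and 4, 2 gave as many genes, the real one included. The real one gave 692 genes, with macrophage diet in the fit. The highest other, 2597 genes, set the 4 exposed chow macrophage arrays apart and so follows a structure of the samples. Most splits part the 2 arrays of a group, which widens the residual spread and favours any split along whole groups. The test argues against a random division of single arrays, but cannot exclude chance differences between groups. A uniform shift of all values by the globin signal, which would move genes alike, is argued against by the 43 members of the erythroid, neutrophil and platelet lists, whose changes with any RBC had an SD of 1.15 (from -0.25 to 5.76) against a median SE of 0.08. The spread of these lists had been seen before this test, and a globin effect that differs between genes was not tested. A candidate explanation is RNA of neutrophils and platelets carried in with the RBC: panels of 24 neutrophil and 22 platelet genes outside the lists and named genes lay at the 96.84 percentile or higher of 10000 random lists matched on expression, in both macrophage diets (taken by RBC diet, the neutrophil panel was at 93.78 in chow macrophages with chow RBC), though the median rises were small (0.0458 and 0.13 for the neutrophil and 0.17 and 0.10 for the platelet panel in chow and high-fat macrophages), 3 and 8 genes were called (Trem1, Asprv1 and Pglyrp1; Nrgn, F5, Cavin2 and Pdlim1 among the 8), and 10 and 8 panel genes lie above the median of all genes in unexposed macrophages. The random lists were drawn gene by gene, without the correlation between genes of 1 cell type, so these percentiles can be too high. Markers of B, T and NK cells did not rise with those of neutrophils and platelets (0 of 14 B cell markers rose and 5 fell, and 0 of 16 T and NK cell markers rose and 1 fell). The falls of Ms4a1 and Cd79b were larger in chow macrophages (differences of 0.90 and 0.61). Unexposed chow macrophages also held more Cd79a (5.38 and 5.94, against 3.65 and 3.29 in unexposed high-fat macrophages), so these falls do not tell what came with the RBC. Induction of S100a9 and other such genes in the macrophages themselves was not tested and stays open.

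Between macrophage diets 2648 genes differed. Of 100 splits of the arrays into 6 and 6, 1 gave as many genes as the real one, which is the real one itself. It gave 1924 genes with RBC condition in the fit, and the highest other gave 1. Most of these splits also part the 2 arrays of a group. The test thus argues against a random division of single arrays, but cannot exclude chance differences between groups or donors. Genes on X and Y made up 3.17% of the called genes. Only 739 X-linked and 9 Y-linked genes were tested, too few to be the bulk of 2648 in any case. This share therefore decides nothing about an effect of sex on autosomal genes. Donor sex and diet cannot be told apart, because Xist and Eif2s3y gave the female pattern on every chow and the male pattern on every high-fat macrophage array, 12 of 12; the labels do not state sex. The diet of the donors therefore stays an open explanation beside their sex, and an error in the labels of whole groups, which was not tested, stays open too.

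The response to RBC differed between macrophage diets in 1131 genes, with interferon and NF-kB genes falling in chow and rising in high-fat macrophages. Each response is taken against 2 unexposed arrays, which themselves differed by diet. Ifit1 was at 8.51 and 8.23 in unexposed chow and 4.08 and 3.86 in unexposed high-fat macrophages. With RBC it lay between 6.24 and 7.11 and between 5.45 and 6.06. For such genes the interaction equals a diet difference that shrank with RBC. Leaving out 1 array at a time does not test both unexposed chow arrays, which lay apart on the first principal component (-32.5 and -34.1). The unexposed high-fat array that stood apart (replicate 1) is argued against as the cause by 1051 genes without it, and narrower intensity distributions on unexposed arrays by 1241 genes after quantile normalization. Dependence on a single unexposed chow array could explain part of the count: it was 813 without replicate 1 and 558 without replicate 2, the latter under the limit written before that test, but the interferon-stimulated genes list kept its call (adjusted p = 4.6e-36 and 3.7e-50). A difference in how macrophages of the 2 diets, or of the 2 sexes, meet RBC was not tested apart and stays open.

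Each value that follows is a difference between the macrophage diets in the response to RBC (high-fat minus chow, log2) with an adjusted p below 0.05 in the interaction test. Among the genes the text names for RBC exposure or this interaction, the largest positive ones were Cxcl2 5.07, Acod1 5.02, Ifit3 3.64, Ptges 3.58, Ifit1 3.55, Rtp4 3.48, Ifi205 3.33, Hp 2.96, Traf1 2.40 and Icam1 2.00. The differences were Tnf 2.00, Flrt3 1.80, Sod2 1.65, Il1b 1.64, Gadd45b 1.61, Ccl3 1.60, H2-Aa 1.24, Slc13a3 1.18, Osbpl3 1.15 and Cd86 1.14. Smaller ones were Asns 1.10, H2-Eb1 1.07, Cd40 1.06, Nupr1 1.06, S100a9 1.04, Ly6i 1.00, Radx 0.94, Ms4a1 0.90, Abcc1 0.89 and Tmem178 0.87. Next came Abca1 0.77, Egr1 0.73, Vcam1 0.62, Cd79b 0.61, Fcgr1 0.57, Mthfd2 0.50 and Trib3 0.45. Negative differences were Cryab -0.54, Mt2 -0.60, Ube2c -0.65, Col1a2 -0.65, Cdk1 -0.83, Mmp8 -0.89, Top2a -0.99, Cytip -1.07, Ccn1 -1.08 and Ccn2 -1.40. Below these were Bub1 -1.49, Ankrd1 -1.52, Cmbl -1.67, Acta2 -1.79 and Myl9 -2.02. By gene list called in camera, the median difference was 1.37 for interferon-stimulated genes, 1.10 for inflammatory cytokines and NF-kB targets, 0.54 for chemokines, 0.66 for antigen presentation and costimulation and 0.31 for immediate early genes. It was 0.25 for NRF2 and heme response, 0.21 for B cell markers, 0.30 for macrophage identity, 0.0607 for iron handling, 0.16 for alternative activation, 0.0728 for LXR targets and cholesterol efflux and 0.24 for platelet markers. Among lists called more negative it was -0.50 for cell cycle, -0.17 for mesothelial and fibroblast markers, -0.15 for oxidative phosphorylation and -0.13 for lipid uptake/storage and oxidation. With an estimated correlation 6 of these 16 lists stayed called (interferon-stimulated genes, inflammatory cytokines and NF-kB targets, cell cycle, chemokines, antigen presentation and costimulation and immediate early genes; adjusted p from 5.2e-04 to 0.012), and the other 10 did not (adjusted p from 0.084 to 0.56). For the interaction of RBC diet with macrophage diet the lists called by camera had medians of 0.10 (glycolysis and hypoxia response) and 0.16 (neutrophil markers). Neither was called with an estimated correlation (adjusted p = 0.93 and 0.21), and each lost its call without 1 array of the chow macrophages with chow RBC (0.26 without replicate 1 and 0.053 without replicate 2).

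Among 13767 probe sets without a single gene symbol, which enter no comparison of genes, 15 passed for RBC exposure and 166 for macrophage diet.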

How the results depend on the processing

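Removal of X and Y genes, the animal block within diet for gene lists and the explicit fit without replicate 1 of the unexposed high-fat macrophages (the same fit as its omission in turn) were added after the result was seen; all other alternatives were planned. Each array left out leaves its group with 1 array, which is assumed to vary like the other groups. The 14 counts stayed within 1.5 times their value after quantile normalization, removal of the lowest genes, the mean of probe sets and removal of X and Y genes, although a count does not say which genes. Signal over background was not analysed here, which limits what can be said of low signals. Of 3144 values of named genes with an array left out, 3037 kept direction and side of the threshold, 81 lost and 9 gained a call and 17 changed sign. The genes named were picked after their results were seen, so this share is no measure for all genes. Over all called genes that the naming rule allows, 870 of 9564 values lost their call. With an estimated correlation 26 of 86 list values lost their call. In fry 11 of the 86 lost and 2 gained a call and 1 changed direction. After quantile normalization 4 lost and 1 gained a call and 3 changed direction. The fit to the compared arrays only was not run for the 3 comparisons that use all 12 arrays.

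With a 1.5-fold minimum, which calls fewer genes by construction, the counts were 172 for any RBC, 749 for chow RBC in chow macrophages, 679 for high-fat RBC in chow macrophages, 380 for macrophage diet, 1187 for macrophage diet without RBC and 246 for macrophage diet with chow RBC. With adjusted p below 0.10, which calls more, they were 2547 for any RBC, 2623 for high-fat RBC in chow macrophages, 201 for chow RBC in high-fat macrophages, 7 for RBC diet and 755 for macrophage diet with chow RBC. Array weights gave 2872 for high-fat RBC in chow macrophages, 84 for chow RBC in high-fat macrophages, 78 for high-fat RBC in high-fat macrophages, 5 for RBC diet, 9 for RBC diet in high-fat macrophages and 441 for macrophage diet with high-fat RBC. An intensity trend with robust eBayes gave 201 for chow RBC in high-fat macrophages, 11 for RBC diet, 13 for RBC diet in high-fat macrophages and 417 for macrophage diet with high-fat RBC. Fits to the compared arrays only, which have fewer degrees of freedom, gave 44 for chow RBC in high-fat macrophages, 38 for high-fat RBC in high-fat macrophages, 0 for RBC diet in high-fat macrophages, 1777 for macrophage diet without RBC, 315 for macrophage diet with chow RBC and 1 for RBC diet by macrophage diet. In chow macrophages such fits gave 1582 for chow and 2096 for high-fat RBC, in place of 1830 and 1663. Fewer degrees of freedom thus did not lower every count. The 2 unexposed high-fat arrays differed most from each other, with an SD of their difference across genes of 0.24, against 0.151 to 0.19 in the other groups. The 2 arrays of a group got equal weights. These were lowest for unexposed high-fat macrophages (0.544) and highest for chow macrophages with high-fat RBC (1.56), so the weights act on whole groups. Beyond these values the cause was not tested for array weights, nor was it for the trend.

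With the animal number as a replicate block over all groups the counts were 1354 for any RBC, 2581 for macrophage diet, 2 for RBC diet and 1059 for the interaction with exposure, with 1 for RBC diet in chow macrophages in place of 0. With the block within diet they were 1 for RBC diet, 2 for RBC diet in chow macrophages and 3 for RBC diet in high-fat macrophages; the cause was not tested. Whether the numbers pair samples within a macrophage diet is not settled: residuals of equal numbers had r over 0.1 in 2 of 6 pairs of groups within a diet (range -0.0774 to 0.344) and in the same 2 of all 15 pairs, and the samples were treated as unpaired.

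With each array left out in turn, the counts ranged from 681 to 2812 for any RBC, 726 to 2237 for chow RBC in chow macrophages, 710 to 2142 for high-fat RBC in chow macrophages, 54 to 458 for chow RBC in high-fat macrophages, 66 to 290 for high-fat RBC in high-fat macrophages, 1 to 4 for RBC diet and 0 to 2 for RBC diet in chow macrophages. They ranged from 0 to 6 for RBC diet in high-fat macrophages, 1980 to 2875 for macrophage diet, 1600 to 2746 for macrophage diet without RBC, 181 to 610 for macrophage diet with chow RBC, 121 to 348 for macrophage diet with high-fat RBC, 0 to 1 for RBC diet by macrophage diet and 558 to 1115 for exposure by macrophage diet. The cause was not tested.

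Named genes that changed sign in some fits were uncalled, and the fits gave log2 values as follows. With any RBC these were Ccl2 (-0.0207 after quantile normalization, -0.15 to 0.197 with arrays left out) and Nos2 (-0.19 to 0.0392 with arrays left out), and with chow RBC in chow macrophages Abca1 (-0.0135 after quantile normalization, -0.0984 to 0.108 with arrays left out). For RBC diet they were Tnf (-0.127 to 0.00675 with arrays left out), Arg1 (-0.193 to 0.0525 with arrays left out), Abca1 (-0.0217 to 0.0814 with arrays left out), Hmox1 (-0.0796 to 0.0209 with arrays left out) and Nos2 (-0.00253 to 0.125 with arrays left out). For macrophage diet they were Il6 (-0.0185 to 0.154 with arrays left out) and Nos2 (-0.0543 to 0.0987 with arrays left out). Among lists with any RBC, those that changed direction had adjusted p values of erythroid transcripts (0.81 after quantile normalization), unfolded protein and integrated stress response (0.108 to 0.889 with arrays left out), NRF2 and heme response (0.065 to 0.945 with arrays left out), dendritic cell markers (0.117 to 0.889 with arrays left out), T and NK cell markers (0.872 after quantile normalization), eosinophil markers (0.499 to 0.979 with arrays left out) and mast cell and basophil markers (0.829 in fry, 0.448 after quantile normalization, 0.437 to 0.972 with arrays left out). The cause was not tested.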

Other observations

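The form of the test of RBC diet on splits of the arrays, without the split by macrophage diet, was chosen after its result was seen, and no other test in this part was. In high-fat macrophages given RBC, members of the iron handling and matrix lists rose together with neutrophil and platelet markers and globin, and Lcn2 and Slc25a37 are themselves genes of neutrophils and erythroid cells, so the source of these transcripts stays open. Lcn2, which binds iron-loaded siderophores, rose by 1.43 ± 0.13 with chow RBC and 2.38 ± 0.13 with high-fat RBC, and Slc25a37, a mitochondrial iron importer of erythroid cells, by 0.91 ± 0.10 and 0.72 ± 0.10 (2 arrays per group). Hp, the gene of haptoglobin, which binds free hemoglobin, rose by 0.63 ± 0.11 and 0.57 ± 0.11 there against a change of -0.87 ± 0.07 averaged over both macrophage diets, and the iron exporter gene Slc40a1 by 0.97 ± 0.15 with high-fat RBC. Of 22 iron handling genes 3 and 4 rose and 0 fell (3 and 4 higher adjusted over the list alone; adjusted p = 0.033 and 0.026 with an estimated correlation). Of 25 immediate early genes 4 rose with either RBC (7 and 10 adjusted over the list alone; adjusted p = 0.016 and 0.0065 with an estimated correlation). Egr1 rose by 0.65 ± 0.11 and 0.66 ± 0.11, and Nr4a1 by 0.69 ± 0.13 and 0.86 ± 0.13. These calls depend on single arrays. Hp with chow RBC did not pass without replicate 1 of the high-fat macrophages with chow RBC (0.24) or replicate 1 of the unexposed high-fat macrophages (0.15). Hp with high-fat RBC lost its call in 9 of the 12 fits with an array left out (adjusted p from 0.05 to 0.23). Slc40a1 with high-fat RBC did not pass without replicate 1 of the high-fat macrophages with high-fat RBC (0.082). Egr1 with chow RBC did not pass without replicate 1 of the high-fat macrophages with chow RBC (0.095) or replicate 2 of the high-fat macrophages with chow RBC (0.13) or replicate 1 of the unexposed high-fat macrophages (0.12). Egr1 with high-fat RBC did not pass without replicate 2 of the high-fat macrophages with high-fat RBC (0.15) or replicate 1 of the unexposed high-fat macrophages (0.11). Nr4a1 with chow RBC did not pass without replicate 1 of the high-fat macrophages with chow RBC (0.28) or replicate 2 of the high-fat macrophages with chow RBC (0.13) or replicate 2 of the unexposed high-fat macrophages (0.074). Nr4a1 with high-fat RBC did not pass without replicate 1 of the high-fat macrophages with high-fat RBC (0.082). Of 17 matrix and protease genes 4 and 5 rose and 0 and 1 fell (8 and 8 higher adjusted over the list alone), such as the metalloproteinase Mmp19 (1.36 ± 0.11 and 1.42 ± 0.11) and Thbs1 (1.39 ± 0.10 and 1.28 ± 0.10). Camera adjusted p for that list was 5.1e-09 and 5.0e-09, and adjusted p = 0.054 and 0.056 with an estimated correlation.

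Averaged over macrophage diets, some genes for engulfment rose with RBC, though most did not pass. Of 36 engulfment receptors and machinery 8 rose, 2 fell and 26 did not pass (14 and 3 adjusted over the list alone), such as the Fc receptor gene Fcgr1 (0.55 ± 0.06) and the apoptotic cell receptor gene Mertk (0.43 ± 0.07). Of 14 heat shock genes 2 rose (3 and 1 higher and lower adjusted over the list alone), such as Cryab (0.64 ± 0.07) and Hspb1 (0.45 ± 0.10), and of 24 oxidative phosphorylation genes 1 (0 adjusted over the list alone). Camera adjusted p values were 1.8e-04, 0.014 and 2.4e-05, and adjusted p = 0.3, 0.3 and 0.29 with an estimated correlation. Hspb1 did not pass after quantile normalization (adjusted p = 0.064) or without replicate 2 of the unexposed chow (0.12) or replicate 1 of the unexposed high-fat macrophages (0.052). The heat shock list was at 0.053 without replicate 1 of the chow macrophages with chow RBC and 0.056 without replicate 1 of the unexposed high-fat macrophages. LXR targets (2 of 15 higher, 1 lower; 5 and 1 adjusted over the list alone) were not called (adjusted p = 0.071), but were without replicate 1 of the high-fat macrophages with high-fat RBC (0.027) or replicate 2 of the unexposed high-fat macrophages (0.01).

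Markers of further cell types were not called by camera with RBC exposure averaged over macrophage diets. Higher and lower members numbered 2 and 0 of 14 for mesothelial cells and fibroblasts, 0 and 0 of 7 for adipocytes, 1 and 0 of 10 for dendritic cells, 0 and 1 of 16 for T and NK cells, 0 and 0 of 8 for eosinophils, and 1 and 0 of 10 for mast cells and basophils. Adjusted over the list alone the numbers were 3 and 0, 0 and 0, 1 and 0, 0 and 0, 0 and 0, and 1 and 0. Camera adjusted p values ran from 0.071 (mesothelial cells and fibroblasts) to 0.86 (mast cells). The mesothelial and fibroblast list passed without replicate 1 of the chow macrophages with chow RBC, replicate 2 of the unexposed chow macrophages, or replicate 2 of either exposed high-fat group (adjusted p from 0.025 to 0.046) and was called by fry on all arrays (0.023); its collagen gene Col1a2 rose by 0.48 ± 0.06. In chow macrophages alone camera called that list higher with chow and with high-fat RBC (adjusted p = 0.011 and 0.0019, and 0.21 and 0.11 with an estimated correlation), with 3 and 3 of 14 higher and 0 lower (4 and 5 higher adjusted over the list alone). The first call was lost without replicate 2 of the chow macrophages with chow RBC (0.16). Medians and means of the dendritic, T and NK cell and adipocyte lists were below 0; that of mast cells had a median below and a mean above 0.

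A hypothesis on the contractile and matricellular genes is that SRF and YAP, which drive such genes, act more strongly with RBC. A panel of 28 further target genes may fit it. Its median rise was 0.32 with chow RBC and 0.30 with high-fat RBC in chow macrophages. The lower of both percentiles among 10000 random lists matched on expression was 100, though lists drawn gene by gene lack the correlation of related genes. With any RBC 13 of the panel were called higher, such as Cnn1 (1.15), Tpm2 (0.95) and Cald1 (1.00), and 0 lower. The rest did not pass, among them Amotl2 (0.04), Ajuba (0.08), Lats2 (0.12) and Myh9 (0.04). In high-fat macrophages the medians were 0.23 and 0.20, also at percentile 100, and whether the panel differed between the macrophage diets was not tested. Of the panel 19 genes lie above the median of all genes in unexposed macrophages. A share of fibroblasts or other stromal cells, which express these genes and the collagens, was not excluded, and the mesothelial and fibroblast list was called in the same chow macrophage comparisons. RNA carried in with the RBC was not excluded as a source either, as platelet markers rose on the same exposed arrays.

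Whether chance can be excluded for the difference by RBC diet was tested on the 8 exposed arrays, with macrophage diet in the fit. The split by macrophage diet, 1 of 35, equals a term of the fit and was left out. Of the other 34 splits into 4 and 4, 1 gave as many genes as the real one, which is the real one itself, with 1 gene against a highest other of 0. The share is small, but it rests on a single gene and on a form of the test chosen after its result was seen, and 629 genes had an unadjusted p under 0.05 in the comparison on all arrays where 996.9 are expected by chance, so chance is not taken as excluded. On a principal component analysis of the genes, the first component held 42.5% and the second 18.9% of the variance. The unexposed chow macrophage arrays lay at -32.5 and -34.1 on the first, and replicate 1 of the unexposed high-fat macrophages at 23.1 on the second. Replicates of a group correlated at r between 0.994 and 0.997 across genes, which are not independent replicates.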
